A study of Mus musculus with 25 samples.

How the data were processed

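Liver poly-A RNA was sequenced from 25 mice in 8 groups, and per the labels' protocols the groups differed in diet, in the carbon tetrachloride injections and in the dose and timing of mannose. The authors aligned reads with STAR to GRCm39 and counted them per gene with featureCounts 2.0.6, per the submitters' processing notes, while the deposited table's header names featureCounts 2.0.1 and GENCODE release 31, per the file headers. The deposited table holds whole-number counts per gene that the authors had not normalized, with 56980 genes, of which 52073 carry a symbol, 4907 do not, and 135 share a symbol with another. All 25 count columns were matched to samples by name.

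The counting command gives no option for strand, read pairs or reads with several alignments, per the file headers, so by the tool's defaults strand was not used and reads aligned to several places were not counted. Reads of a gene and of an antisense or overlapping gene therefore cannot be told apart. Genes with near-identical copies, such as Serpina1e, Hamp2, the Cyp2c and Cyp4a genes and the Saa genes, are uncertain because reads they share were dropped. The mitochondrially encoded genes had 0 counts in all 25 libraries, so the list of them could not be tested. Replicates are separate mice only as far as the labels say, and cages, litters and collection days are not given in the sources used here.

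Total counts per library were 31298299 to 56010646 in the first batch and 35971380 to 49752882 in the second. The 10 most abundant genes held 16.18% to 19.23% and 19.5% to 24.71% of counts in these batches. No pair of libraries of a group differed by as little as sampling noise (lowest chi-square per degree of freedom 21.2), so each counts as 1 replicate. Where a group had 0 counts, the fold was computed against a floor of 3 counts per library, which covers counting error only.

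Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest) with TMM scaling, the filterByExpr filter, Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p, without a minimum fold. The 18 first-batch libraries were fitted together (19571 genes), the 7 second-batch libraries together (18462 genes), and all 25 with a batch term for the comparisons between diets (21373 genes). Normal diet without mannose was in both batches, so the batch term can be told apart from diet only through those 5 libraries. CPM values are TMM-scaled within a batch. The groups were compared as FAT-MASH against normal diet, each mannose group against FAT-MASH and against normal diet, the mean of the 4 mannose groups against FAT-MASH, 20% against 5%, prevention against therapy, dose by timing, mannose against none on normal diet, and the difference of the mannose effect between diets.

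For gene groups, 37 lists of pathway genes and cell type markers were tested with limma 3.58.1's camera on voom values with a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists of a comparison. A list needed 3 measured members, which left 36. The genes named in the text follow a rule: 19 key genes of sugar, lipid, bile acid, stress and fibrosis biology, the 6 largest rises and 6 largest falls in each comparison among genes past the threshold with a mean of at least 5 CPM, and up to 4 members of a described list with the smallest p. That mean was taken over all libraries of the fit, so a gene low in the groups compared could pass through another group. The rises and falls had to have no overlap between the libraries of the compared groups, which chance gives for 10% of genes with 3 against 3. Predicted or clone names, pseudogenes, immunoglobulin and T cell receptor segments and Mup genes were left out, interactions had no overlap rule, and counts of 5 or fewer genes were named in full. The comparisons, lists, rule and first alternatives were set before the data were examined. Whether that count is taken over a comparison or for each direction was left open then, and it was taken for each direction after the results had been seen, which added Eps8l1 among the 5 genes higher with 5% therapy. Some genes that the rule selects are not reported here.

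The alternatives were DESeq2 1.42.0, edgeR with RLE size factors, no filter on low counts, limma voom with sample quality weights, a fit of only the groups compared, all 25 libraries with a batch term, the replicate number as a block, library totals alone as scaling, and leaving out each library in turn. Added after seeing the data were FAT-MASH replicate 2 as the only FAT-MASH library, the dose within prevention or therapy, and the timing within 5% or 20%. All but library totals were run for the key genes and steepest rises and falls, and not for other list members. With library totals alone as scaling the median log2 fold change over all genes was 0.20 for 20% prevention and 0.30 for 20% therapy.

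The test was tried on simulated counts with known changes in 67, 67 and 66 genes at 1.5, 2 and 4-fold. For 20% prevention against FAT-MASH (18962 genes) it recovered 13.4%, 65.7% and 77.3% of them with 5.2% false calls. For 20% mannose on normal diet (17414 genes) it recovered 4.5%, 37.3% and 63.6% with 9.1% false calls, and for the difference between diets at 20% (20459 genes) 1.5%, 25.4% and 53% with 3.6%. As the mannose comparisons share the FAT-MASH libraries, unchanged groups were simulated for the opposite-sign share and covariance that sharing gives.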

Results

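The series holds RNA-seq of poly-A RNA from the livers of male C57BL/6J mice that were 8 weeks old at the start. The FAT-MASH regimen, a mouse model of metabolic dysfunction-associated steatohepatitis, joined a chow rich in fat, sucrose and cholesterol to sugar water and weekly carbon tetrachloride, a liver toxin, for 12 weeks. Mannose, a hexose sugar, was given in the drinking water at 5% or 20%, either for all 12 weeks (prevention) or for the last 6 weeks (therapy). The first batch has 18 libraries in 6 groups of 3: normal diet, FAT-MASH, and FAT-MASH with 5% prevention, 20% prevention, 5% therapy or 20% therapy. The second batch has 7 libraries of mice on normal diet: 2 without mannose, 2 with 5% and 3 with 20%.

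In the principal component analysis of the first batch, the first component held 31.7% of the variance and set the 3 normal-diet libraries apart from the other 15. Levels are in CPM, counts scaled to a common library total, as the group mean ± SD with n = 3, and log2 fold changes are given ± SE. Positions are on GRCm39. Unless another test is named, a gene rose or fell where it passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Where a call turned on 1 library or setting, the word alternatives precedes the range of adjusted p over all alternative settings and left-out libraries. Its low end is no support, as adjusted p of named genes fell far without a filter on low counts, for untested reasons.

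**Figure D1:**
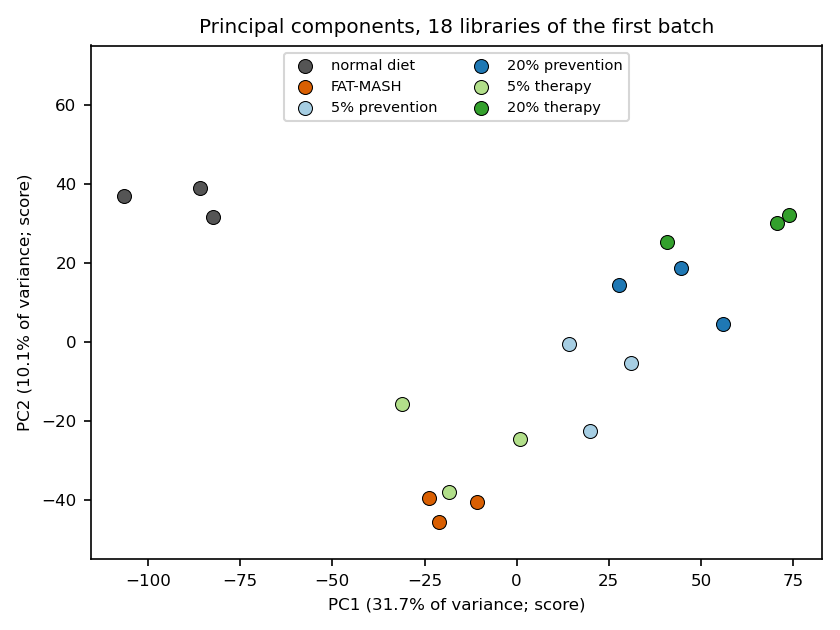
Position of each of the 18 first-batch libraries on the first principal component (31.7% of the variance) and the second (10.1%) of log2 CPM, with 1 point per library coloured by group. The normal-diet libraries lie between -106.4 and -82.3 on the first component and the 20% therapy libraries between 40.8 and 73.8.

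The first comparison tested the regimen alone. Cholesterol synthesis had 23 of 24 measured genes lower, 0 higher, and a median log2 fold change of -2.32 (23 lower adjusted over the list alone). Sqle, the squalene epoxidase of that pathway (ENSMUSG00000022351.15, chromosome 15, 59186926 to 59203041), went from 128 ± 10.4 to 5.51 ± 1.21 CPM, a log2 fold change of -4.55 ± 0.27. Msmo1 (-3.81 ± 0.17), Hmgcs1 (-2.71 ± 0.17), Hsd17b7 (-2.62 ± 0.13) and Mvd (-3.95 ± 0.29), other enzymes of the pathway, fell too. Genes more active in male than in female liver fell in 14 of 16 cases (15 adjusted over the list alone), among them Susd4 (-5.83 ± 0.44), the steroid dehydrogenase gene Hsd3b5 (-5.64 ± 0.54), Cyp7b1 (-2.74 ± 0.29) and Serpina1e (-6.62 ± 0.77), a member of a family of near-identical genes. Pericentral hepatocyte markers fell in 7 of 15 cases and rose in 1 (10 and 1 adjusted over the list alone), led by Lhpp (-3.21 ± 0.28), Oat (-3.51 ± 0.34) and the glutamine synthetase gene Glul (-1.72 ± 0.19). By limma's camera the adjusted p of these 3 lists was 1.62e-55, 3.65e-19 and 7.92e-09, and with an estimated correlation it was 0.00242, 0.0365 and 0.0365.

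Genes of fibrosis and inflammation rose on the regimen. Extracellular matrix genes were higher in 20 of 34 cases (30 adjusted over the list alone; median 1.15), including the collagen gene Col5a2 (2.18 ± 0.39), Lum (1.81 ± 0.38) and the metalloprotease gene Mmp14 (0.85 ± 0.14). Timp1, an inhibitor of matrix proteases, rose by 3.40 ± 0.71. The collagen gene Col1a1 went from 10.3 ± 6.61 to 37.8 ± 9.07 CPM (1.87 ± 0.55), while Acta2, the smooth muscle actin of activated stellate cells, did not pass (-0.34 ± 0.51). Markers of recruited and lipid-associated macrophages rose in 11 of 20 cases (13 adjusted over the list alone; median 1.64), among them Trem2 (3.36 ± 0.70), Lpl (3.06 ± 0.30), Cd63 (2.99 ± 0.29) and Clec7a (2.91 ± 0.43). Among these markers, Gpnmb reached 42.5 CPM in normal diet replicate 2, against a group mean of 14.3 ± 24.4, and did not pass (1.70 ± 1.05). Inflammatory signalling genes rose in 10 of 26 cases (15 adjusted over the list alone), for example Vcam1 (2.17 ± 0.33) and Tnfaip3 (1.63 ± 0.30). All 3 lists passed limma's camera (adjusted p from 3.64e-09 to 8.69e-05) and lost that call with an estimated correlation (adjusted p from 0.30 to 0.351). Without normal diet replicate 2 the log2 fold change was 8.21 for Gpnmb and 5.29 for Trem2. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, single libraries decided the calls of Col1a1 (lost without normal diet replicate 1 or 3 or FAT-MASH replicate 2 or 3, adjusted p 0.0758 to 0.126, alternatives 9.53e-40 to 0.126) and Gpnmb (gained without normal diet replicate 2, adjusted p 0.000213, alternatives 6.95e-32 to 0.603).

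Steep single rises lay outside those groups. H19, an imprinted noncoding RNA of fetal liver (ENSMUSG00000000031.18, chromosome 7, 142129262 to 142131886), rose by 7.67 ± 1.23, Rgs16, a regulator of G-protein signalling, by 6.29 ± 0.62, and Rad51b, a recombination gene (ENSMUSG00000059060.16, chromosome 12, 79344056 to 79861464), by 5.67 ± 0.28. Eda2r (5.53 ± 0.43), a p53 target, and Ly6d (5.06 ± 0.39), a surface protein gene of the oncofetal list, followed. Sprr1a, a gene of the cornified envelope, had 0 counts in all 3 normal-diet libraries and 0.69 CPM in FAT-MASH, at least 7.8-fold higher against a floor of 3 counts per library, so its rank among the rises is not known. Among the p53 and senescence genes 8 of 16 rose and 1 fell (10 and 2 adjusted over the list alone), with Cdkn1a at 2.83 ± 0.36 and Phlda3 at 3.15 ± 0.44. Fatty acid oxidation and PPAR alpha targets rose in 17 of 26 cases (17 adjusted over the list alone), such as Cpt1a (1.14 ± 0.13) and Bdh1 (1.16 ± 0.12). The hormone gene Fgf21 rose by 4.66 ± 0.68 and the stress cytokine gene Gdf15 by 1.04 ± 0.25. The transporter gene Slc22a28 fell by 4.44 on the log2 scale. The 2 lists passed limma's camera (adjusted p 0.000283 and 3.82e-11), but not with an estimated correlation (adjusted p = 0.268 and 0.053). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, single settings decided the calls of Sprr1a (lost without normal diet replicate 1, 2 or 3 or FAT-MASH replicate 3, adjusted p 0.102 to 0.173, lost with voom, adjusted p 0.196, alternatives 2.12e-19 to 0.362) and H19 (lost with voom, adjusted p 0.103, alternatives 8.68e-87 to 0.103). Fgf21 (lost with voom, adjusted p 0.0539, alternatives 5.03e-120 to 0.0539) and Gdf15 (lost without normal diet replicate 3, adjusted p 0.0502, alternatives 9.71e-12 to 0.0541) had calls that changed likewise.

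The series is about fructose metabolism. Khk, the kinase that commits fructose to metabolism (ENSMUSG00000029162.16, chromosome 5, 31078775 to 31088592), rose from 500 ± 57.9 to 827 ± 15.2 CPM on the regimen (0.73 ± 0.17). Tkfc, a triose kinase of the same pathway (ENSMUSG00000034371.10, chromosome 19, 10565155 to 10583018), went from 383 ± 53 to 671 ± 78.3 CPM (0.81 ± 0.15). The transporter gene Slc2a2 (0.62 ± 0.14) rose too. In all, 4 of 12 fructose handling genes rose and 0 fell (4 and 0 adjusted over the list alone). Mpi, which turns mannose 6-phosphate into fructose 6-phosphate (ENSMUSG00000032306.15, chromosome 9, 57451539 to 57460046), fell from 15.2 ± 1.77 to 9.82 ± 1.68 CPM (-0.62 ± 0.15). The phosphomannomutase gene Pmm1 fell by 2.42 on the log2 scale, while Pmm2 did not pass (-0.28 ± 0.10). Of the lipid synthesis genes, the desaturase Scd1 rose (1.61 ± 0.20) and the fatty acid synthase Fasn did not pass (-0.62 ± 0.29), with 7 of 23 lipogenic genes higher and 8 lower (7 and 9 adjusted over the list alone). Pklr, the liver pyruvate kinase, rose (0.91 ± 0.21). The bile acid enzyme Cyp7a1 (0.63 ± 0.29) and the sugar-sensing factor gene Mlxipl (0.00 ± 0.20) did not pass. In all, 2687 of 19571 genes passed edgeR's test, 1528 higher and 1159 lower. The fructose handling list passed limma's camera (adjusted p = 0.0335), but not with an estimated correlation (adjusted p = 0.351). Leaving out 1 library, or voom where named, changed the camera call of the fructose handling list (lost without normal diet replicate 1 or FAT-MASH replicate 2 or 3, adjusted p 0.054 to 0.0797, alternatives 0.0137 to 0.351) and the edgeR calls of Pmm2 (gained without normal diet replicate 1, adjusted p 0.0325, alternatives 0.0325 to 0.42) and Fasn (gained without FAT-MASH replicate 2, adjusted p 0.0202, alternatives 1.07e-05 to 1). Pklr (lost without FAT-MASH replicate 2, adjusted p 0.0526, alternatives 1.8e-11 to 0.0526) and Cyp7a1 (gained without FAT-MASH replicate 1, adjusted p 0.0465, alternatives 1.51e-05 to 0.672) had calls that changed likewise.

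**Figure D2:**
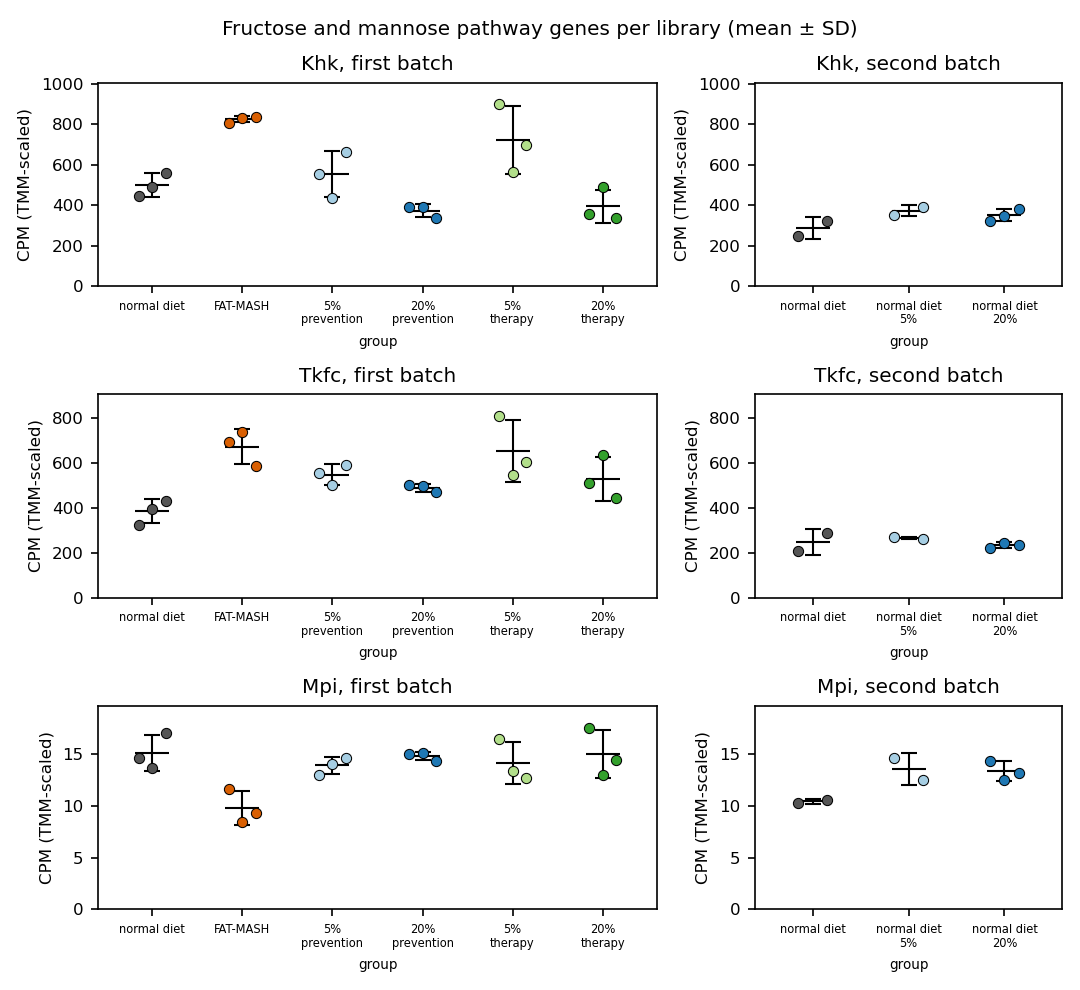
TMM-scaled CPM (vertical axes, linear from 0) of Khk, Tkfc and Mpi per library in the groups of the first batch (left) and second batch (right), with lines and bars for mean ± SD. The mean of Khk was 827 CPM in FAT-MASH, 373 with 20% prevention and 394 with 20% therapy, and that of Mpi 9.82, 14.8 and 15.0 CPM.

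Next was 20% mannose over all 12 weeks on the regimen. Genes of cell division rose: 21 of 24 cell cycle genes were higher and 0 lower, with a median log2 fold change of 2.09 (21 higher adjusted over the list alone). Hmmr, a spindle gene (ENSMUSG00000020330.17, chromosome 11, 40592222 to 40624249), went from 0.276 ± 0.0764 to 7.47 ± 1.32 CPM (4.78 ± 0.58). Cdc20 (3.88 ± 0.51) and Ube2c (3.87 ± 0.42), which act in mitotic exit, Racgap1 (3.48 ± 0.44), Knstrn (3.35 ± 0.45) and Ckap2 (3.13 ± 0.49) made up the 6 steepest rises among genes of at least 5 CPM. The cholangiocyte markers rose in 6 of 12 cases (7 adjusted over the list alone), for example Epcam (2.08 ± 0.47). Inflammatory signalling genes rose in 10 of 26 cases (11 adjusted over the list alone), such as Relb (1.28 ± 0.23) and Il1rn (1.54 ± 0.34). By limma's camera the adjusted p of these 3 lists ran from 6.62e-12 to 0.00439, and with an estimated correlation from 0.266 to 0.562. A single library decided the camera call of the cholangiocyte markers list (lost without 20% prevention replicate 3, adjusted p 0.0572, alternatives 0.000271 to 0.562).

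Fructose handling went the other way with 20% prevention: 9 of 12 genes fell and 0 rose (9 and 0 adjusted over the list alone; median -0.52). Khk fell from 827 ± 15.2 to 373 ± 32.7 CPM (-1.15 ± 0.17). The fructose transporter gene Slc2a5 (-2.01 ± 0.36), Sord (-0.51 ± 0.09), which makes fructose from sorbitol, and Tkfc (-0.46 ± 0.15) fell as well. Beside these falls, the 100 genes with the highest mean CPM had a median log2 fold change of -0.40. Gluconeogenesis genes fell in 9 of 12 cases (10 adjusted over the list alone), such as Fbp1 (-0.77 ± 0.13) and Pck1 (-1.34 ± 0.25). Periportal markers fell in 10 of 14 cases (11 adjusted over the list alone), such as the serine dehydratase gene Sds (-2.62 ± 0.31) and Gls2 (-1.31 ± 0.17). Bile acid synthesis and transport genes fell in 12 of 21 cases and rose in 1 (15 and 1 adjusted over the list alone), with Nr0b2 at -1.77 ± 0.22 and Slc10a1 at -1.30 ± 0.17. Acute phase genes fell in 12 of 23 cases (12 adjusted over the list alone), such as Serpina3n (-1.10 ± 0.13). The adjusted p of these 5 lists by limma's camera ran from 5.99e-10 to 8.7e-05, and with an estimated correlation from 0.112 to 0.279. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, single libraries decided the call of Tkfc (lost without FAT-MASH replicate 1 or 2 or 20% prevention replicate 1, 2 or 3, adjusted p 0.0948 to 0.184, alternatives 0.0047 to 0.184).

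Single genes filled in the picture of 20% prevention. H19 (-4.49 ± 0.95), Hsd3b5 (-3.51 ± 0.62), the transporter gene Slc22a7 (-2.97 ± 0.43), the carbonic anhydrase gene Car1 (-2.49 ± 0.30) and Hamp2 (-2.48 ± 0.48), a near copy of the hepcidin gene, were with Sds the 6 steepest falls. Mpi rose from 9.82 ± 1.68 to 14.8 ± 0.378 CPM (0.59 ± 0.15), Mlxipl fell (-1.12 ± 0.20), Pmm2 fell (-0.32 ± 0.10), Pklr fell (-0.68 ± 0.21) and Fgf21 rose (1.83 ± 0.49). Extracellular matrix genes rose in 1 of 34 cases, Col4a1 (0.79 ± 0.23), and in 0 adjusted over the list alone, and recruited macrophage markers in 2 of 20, Spp1 (1.72 ± 0.43) and Cd9 (0.57 ± 0.14), and in 2 adjusted over the list alone. Their adjusted p by limma's camera was 0.0256 and 0.0898, and 0.684 for both with an estimated correlation. The matrix call was lost without FAT-MASH replicate 1 (camera adjusted p 0.22) or 20% prevention replicate 3 (0.835, median -0.08; alternatives 0.000521 to 0.835). The key genes of these groups did not pass: Col1a1 was at 0.53 ± 0.52, Timp1 at 0.52 ± 0.57, Acta2 at 0.24 ± 0.50, Trem2 at -0.09 ± 0.60 and Gpnmb at -0.07 ± 1.01. Fasn (0.46 ± 0.29), Scd1 (0.25 ± 0.19), Cyp7a1 (0.11 ± 0.29), Gdf15 (-0.12 ± 0.24) and Pmm1 (0.94 ± 0.43) did not pass either. In all, 2952 of 19571 genes passed edgeR's test, 1336 higher and 1616 lower, against 1938 without 20% prevention replicate 2. With 1 library left out, or with voom where named, the edgeR calls changed for Mpi (lost without FAT-MASH replicate 2, adjusted p 0.0642, alternatives 0.00195 to 0.0642) and Pmm2 (lost without FAT-MASH replicate 1, 2 or 3 or 20% prevention replicate 1, 2 or 3, adjusted p 0.0569 to 0.106, alternatives 0.0172 to 0.23). Pklr (lost without FAT-MASH replicate 2 or 20% prevention replicate 1, 2 or 3, adjusted p 0.0758 to 0.21, alternatives 1.89e-06 to 0.21) and Fasn (gained without FAT-MASH replicate 2, adjusted p 0.0496, alternatives 0.00194 to 0.884) had calls that changed likewise. Fgf21 (lost without FAT-MASH replicate 2 or 3 or 20% prevention replicate 2, adjusted p 0.0638 to 0.106, alternatives 6.46e-34 to 0.106) had calls that changed likewise.

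The same dose was also tested as therapy. All 24 cell cycle genes rose, with a median log2 fold change of 3.44 (24 adjusted over the list alone). Hmmr reached 18.7 ± 10.2 CPM (6.11 ± 0.59), and Ube2c (5.47 ± 0.44), Cdc20 (5.35 ± 0.53), Racgap1 (4.63 ± 0.45) and the spindle gene Tpx2 (4.59 ± 0.55) were among the 6 steepest rises together with Sprr1a (5.20 ± 0.91). Mki67, the proliferation marker, went from 2.86 ± 1.08 to 55.9 ± 29.3 CPM. Inflammatory signalling genes rose in 13 of 26 cases (16 adjusted over the list alone), such as Il1rn (2.15 ± 0.34) and Cd14 (2.06 ± 0.34). Extracellular matrix genes rose in 10 of 34 cases (14 adjusted over the list alone), led by the basement membrane collagen genes Col4a1 (1.28 ± 0.23) and Col4a2 (1.01 ± 0.23). Oncofetal genes rose in 8 of 13 cases and fell in 1 (9 and 1 adjusted over the list alone), with Anxa5 at 1.47 ± 0.16 and Sox4 at 1.90 ± 0.31. Cholangiocyte markers rose in 8 of 12 cases (8 adjusted over the list alone), with Epcam at 2.79 ± 0.48. Cholesterol synthesis genes rose in 12 of 24 cases and fell in 1 (13 and 2 adjusted over the list alone), with Sqle at 1.67 ± 0.25. By limma's camera the adjusted p of these 6 lists ran from 4.9e-20 to 0.00201, and with an estimated correlation from 0.096 to 0.531.

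Fructose handling genes fell in 9 of 12 cases with 20% therapy and rose in 0 (10 and 0 adjusted over the list alone; median -0.62). Khk was at 394 ± 83.6 CPM (-1.07 ± 0.17), and Slc2a5 (-2.20 ± 0.36), Slc2a9 (-0.91 ± 0.10) and Sord (-0.90 ± 0.09) fell, while Tkfc did not pass (-0.34 ± 0.15). Beside these falls, the 100 genes with the highest mean CPM had a median of -0.61. Bile acid genes fell in 16 of 21 cases (18 adjusted over the list alone), among them Akr1d1 (-1.77 ± 0.16), Slc27a5 (-1.54 ± 0.13) and the bile acid receptor gene Nr1h4 (-0.78 ± 0.10). Periportal markers fell in 12 of 14 cases (13 adjusted over the list alone), such as Hal (-2.60 ± 0.25) and Sds (-3.22 ± 0.32). Gluconeogenesis genes fell in 9 of 12 cases and rose in 0 (9 and 1 adjusted over the list alone). The xenobiotic targets of CAR and PXR fell in 8 of 16 and rose in 1 (9 and 1 adjusted over the list alone). The adjusted p of these 5 lists by limma's camera ran from 8.1e-14 to 0.000112, and with an estimated correlation from 0.0475, for bile acid genes, to 0.305. Fatty acid oxidation and PPAR alpha targets split, with 4 of 26 higher and 12 lower (5 and 14 adjusted over the list alone), and their median of -0.28 and mean of 0.02 differ in sign (camera adjusted p = 0.0275; 0.513 with an estimated correlation). Single libraries, or voom where named, decided the camera call of the fatty acid oxidation and PPAR alpha targets list (lost without FAT-MASH replicate 2 or 20% therapy replicate 1 or 2, adjusted p 0.0509 to 0.055, alternatives 0.00727 to 0.513) and the edgeR call of Tkfc (gained without 20% therapy replicate 2, adjusted p 0.0336, alternatives 0.0336 to 0.424).

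The steepest falls with 20% therapy were H19 (-4.83 ± 0.97), Car1 (-3.86 ± 0.33), Hsd3b5 (-3.81 ± 0.64), the acid phosphatase gene Acpp (-3.64 ± 0.24), Cyp2c54 (-3.47 ± 0.33), from a family of near-identical genes, and Sds. Mpi rose to 15 ± 2.35 CPM (0.61 ± 0.15), Mlxipl fell (-1.47 ± 0.20) and Fgf21 rose (2.08 ± 0.50). Pmm1 (1.58 ± 0.43) and Fasn (0.89 ± 0.29) rose and Pmm2 fell (-0.32 ± 0.10). Col1a1 (1.29 ± 0.53), Timp1 (1.44 ± 0.57), Acta2 (1.06 ± 0.51), Trem2 (0.07 ± 0.60), Gdf15 (0.50 ± 0.24), Pklr (-0.49 ± 0.21) and Cyp7a1 (-0.72 ± 0.29) did not pass. In all, 4195 of 19571 genes passed edgeR's test, 1989 higher and 2206 lower. Without 20% therapy replicate 2 the log2 fold change of Pmm1 was 0.69, and single libraries decided the edgeR calls of Pmm1 (lost without 20% therapy replicate 2, adjusted p 0.183, lost with voom, adjusted p 0.126, alternatives 6.55e-06 to 0.192) and Pmm2 (lost without FAT-MASH replicate 1 or 2 or 20% therapy replicate 2 or 3, adjusted p 0.0576 to 0.0717, alternatives 0.0149 to 0.191). Fasn (lost without FAT-MASH replicate 1 or 3 or 20% therapy replicate 2 or 3, adjusted p 0.0762 to 0.164, alternatives 2.96e-11 to 0.664) and Col1a1 (gained without 20% therapy replicate 2, adjusted p 0.0281, alternatives 1.56e-21 to 0.48) had calls that changed likewise. Cyp7a1 (gained without FAT-MASH replicate 1, adjusted p 0.0199, alternatives 2.05e-07 to 0.46) had calls that changed likewise.

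**Figure D3:**
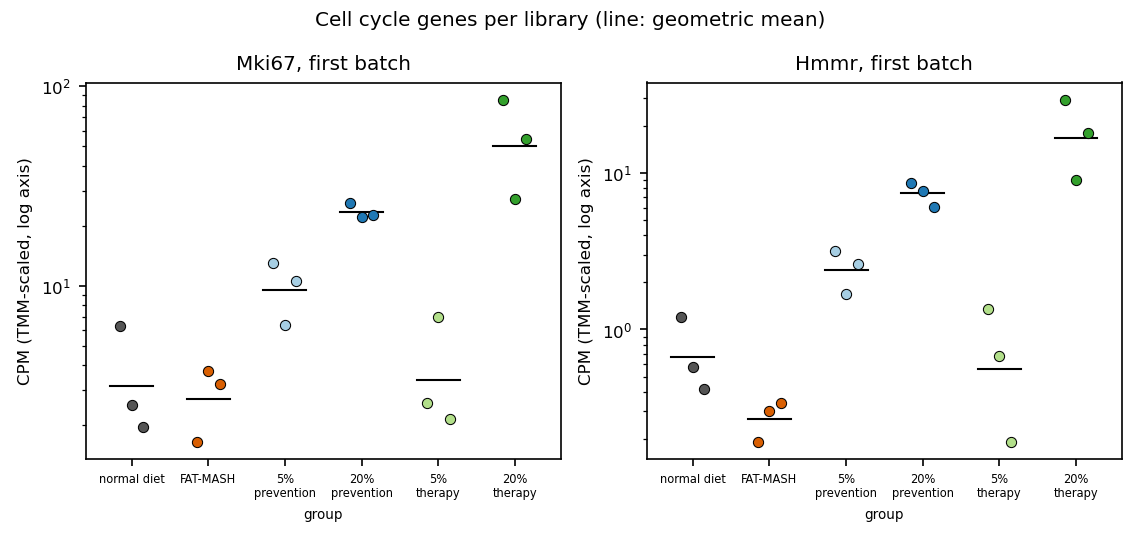
TMM-scaled CPM on a log axis of Mki67 (left) and Hmmr (right) in each first-batch library by group, with 1 point per library and a line at the geometric mean. The arithmetic mean of Mki67 was 2.86 CPM in FAT-MASH, 9.94 with 5% prevention, 23.6 with 20% prevention, 3.91 with 5% therapy and 55.9 with 20% therapy.

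With 5% mannose for 12 weeks, 445 of 19571 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 189 higher and 256 lower. Cell cycle genes rose in 10 of 24 cases and fell in 0 (19 and 0 adjusted over the list alone; median 1.51). Hmmr was at 2.49 ± 0.754 CPM (3.20 ± 0.58), Ube2c at 2.40 ± 0.42 and Racgap1 at 2.38 ± 0.44 on the log2 scale, and Cdc20 (2.42 ± 0.50), the receptor subunit gene Chrna4 (2.71 ± 0.65) and Phlda1 (2.12 ± 0.48) completed the 6 steepest rises. Cholesterol synthesis genes rose in 11 of 24 cases (16 adjusted over the list alone; median 0.69), with Sqle at 1.47 ± 0.25. Lipogenic genes rose in 7 of 23 cases and fell in 2 (11 and 3 adjusted over the list alone), with Pnpla3, a lipid droplet protein gene, at 2.79 ± 0.35 and Fasn at 1.18 ± 0.29. Gluconeogenesis genes fell in 4 of 12 cases (7 adjusted over the list alone), among them Pck1 (-1.47 ± 0.25) and the glucose 6-phosphatase gene G6pc (-1.35 ± 0.25). Fructose handling genes fell in 2 of 12 cases, Slc2a9 (-0.43 ± 0.10) and Slc2a8 (-0.54 ± 0.13), and in 6 adjusted over the list alone. By limma's camera the adjusted p of these 5 lists ran from 3.56e-16 to 2.02e-06, and with an estimated correlation it was 0.0251 for gluconeogenesis and ran from 0.0922 to 0.239 for the other 4. The count fell to 154 without FAT-MASH replicate 1, 265 without FAT-MASH replicate 2, 127 without 5% prevention replicate 1 and 289 without 5% prevention replicate 3. Single settings decided the edgeR calls of Hmmr (lost with voom, adjusted p 0.128, alternatives 4.44e-19 to 0.311) and Ube2c (lost with voom, adjusted p 0.173, alternatives 1.74e-17 to 0.19). Racgap1 (lost with voom, adjusted p 0.0875, alternatives 1.08e-14 to 0.128) and Cdc20 (lost without FAT-MASH replicate 1 or 2 or 5% prevention replicate 1 or 3, adjusted p 0.05 to 0.0918, lost with voom, adjusted p 0.101, alternatives 3.64e-25 to 0.29) had calls that changed likewise. Chrna4 (lost without FAT-MASH replicate 1 or 3 or 5% prevention replicate 1 or 3, adjusted p 0.09 to 0.146, alternatives 1.76e-35 to 0.573) and Phlda1 (lost without FAT-MASH replicate 1, 2 or 3 or 5% prevention replicate 1 or 3, adjusted p 0.0547 to 0.0989, alternatives 5.05e-51 to 0.453) had calls that changed likewise. Fasn (lost without FAT-MASH replicate 1 or 3 or 5% prevention replicate 1 or 3, adjusted p 0.123 to 0.165, alternatives 3.64e-18 to 0.626) had calls that changed likewise.

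The bile acid enzyme gene Cyp7a1 fell with 5% prevention, from 114 ± 49.2 to 33.5 ± 7 CPM (-1.76 ± 0.30), and bile acid genes fell in 3 of 21 cases (10 adjusted over the list alone; camera adjusted p = 2.71e-10; adjusted p = 0.0724 with an estimated correlation). The other steep falls were H19 (-4.25 ± 0.94), Rgs16 (-2.81 ± 0.50), Arl4d (-2.36 ± 0.26), the glucocorticoid-induced gene Tsc22d3 (-1.88 ± 0.35) and the inositol phosphate kinase gene Ip6k2 (-1.64 ± 0.23). Khk was at 553 ± 114 CPM (-0.58 ± 0.17, edgeR adjusted p = 0.0815), Tkfc at -0.29 ± 0.15, Mpi at 0.50 ± 0.15 and Mlxipl at -0.71 ± 0.20, none of which passed. Col1a1 (0.69 ± 0.52), Timp1 (0.76 ± 0.57), Trem2 (0.12 ± 0.60) and Fgf21 (0.82 ± 0.49) did not pass. By DESeq2 Khk passed (adjusted p = 0.0238, alternatives 0.000132 to 0.487). Leaving out 1 library, or voom where named, changed the edgeR calls of H19 (lost without FAT-MASH replicate 2 or 3 or 5% prevention replicate 1, 2 or 3, adjusted p 0.0541 to 0.0831, lost with voom, adjusted p 0.0848, alternatives 2.22e-44 to 0.153) and Mlxipl (gained without FAT-MASH replicate 3, adjusted p 0.0146, alternatives 6.93e-07 to 0.33).

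With 5% mannose as therapy, 7 of 19571 genes passed edgeR's test, 5 higher and 2 lower. Aacs, which feeds ketone bodies into lipid synthesis (ENSMUSG00000029482.5, chromosome 5, 125552878 to 125594474), rose from 24.2 ± 4.21 to 69.3 ± 19 CPM (1.52 ± 0.20). Peg10, an imprinted gene (ENSMUSG00000092035.9, chromosome 6, 4747306 to 4760517), rose by 1.44 ± 0.22 and the tubulin gene Tuba1c by 0.73 ± 0.12. Eps8l1, at a mean of 3.02 ± 0.517 CPM, also rose (2.98 ± 0.44). Arl4d (-1.47 ± 0.25) and Ip6k2 (-1.40 ± 0.23) fell. Khk (-0.20 ± 0.17), Mpi (0.53 ± 0.15) and Gdf15 (-1.09 ± 0.25) did not pass. Cholesterol synthesis genes rose in 1 of 24 cases and in 10 adjusted over the list alone, and the acute phase list had 0 of 23 lower and 6 adjusted over the list alone (medians 0.39 and -0.34). By limma's camera their adjusted p was 3.02e-18 and 3.71e-14, and 0.0947 for both with an estimated correlation. At an unadjusted p under 0.05, 1219 genes passed, DESeq2 called 85 (34 higher and 51 lower), and edgeR called 0 without FAT-MASH replicate 1, 43 without FAT-MASH replicate 2 (14 higher and 29 lower) and 2 without FAT-MASH replicate 3. Single settings decided the edgeR calls of Aacs (lost without FAT-MASH replicate 1, adjusted p 0.056, alternatives 3.91e-29 to 1) and Peg10 (lost without FAT-MASH replicate 1 or 3 or 5% therapy replicate 3, adjusted p 0.0709 to 0.109, lost with voom, adjusted p 0.122, alternatives 4.58e-09 to 1). Tuba1c (lost without FAT-MASH replicate 1 or 3 or 5% therapy replicate 1, adjusted p 0.0884 to 0.159, alternatives 1.16e-06 to 1) and Eps8l1 (lost without FAT-MASH replicate 1 or 3, adjusted p 0.0709 to 0.101, lost with voom, adjusted p 0.143, alternatives 1.28e-10 to 1) had calls that changed likewise. Arl4d (lost without FAT-MASH replicate 1 or 3 or 5% therapy replicate 1, 2 or 3, adjusted p 0.0828 to 0.181, lost with voom, adjusted p 0.143, alternatives 3.23e-22 to 1) and Ip6k2 (lost without FAT-MASH replicate 1 or 3 or 5% therapy replicate 1 or 2, adjusted p 0.101 to 0.159, lost with voom, adjusted p 0.0817, alternatives 5.86e-23 to 1) had calls that changed likewise.

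**Figure D4:**
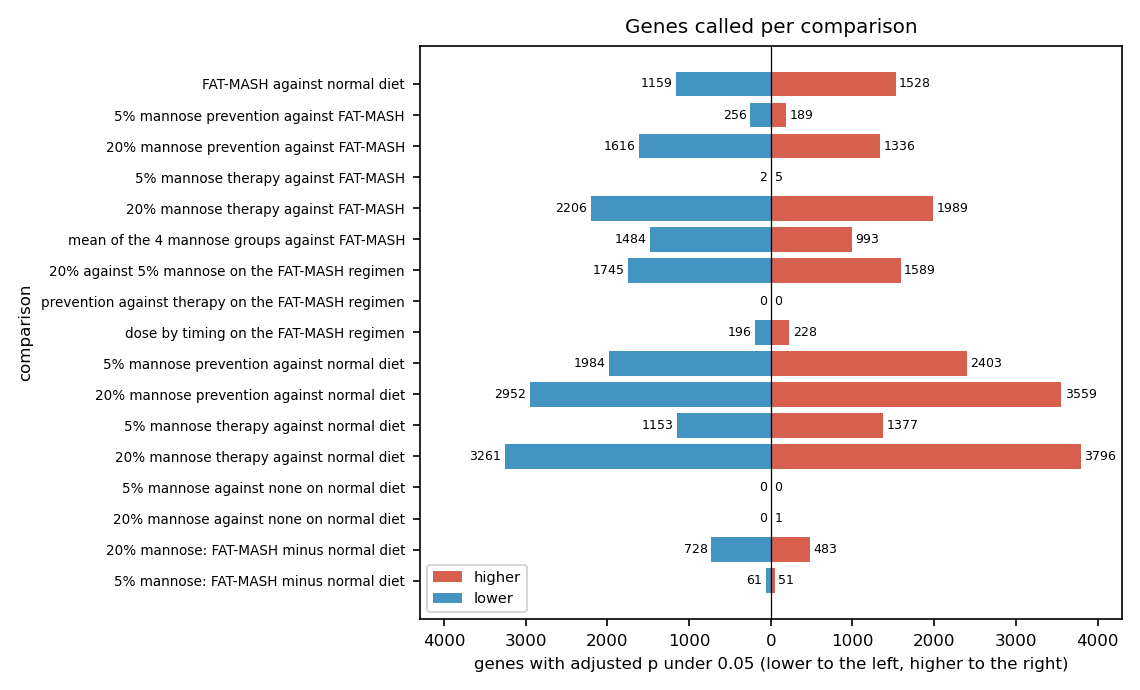
Number of genes (horizontal axis) that were lower (bars to the left) or higher (bars to the right) at an adjusted p under 0.05 by edgeR in each comparison (vertical axis). Therapy with 5% mannose had 5 higher and 2 lower genes against FAT-MASH, and therapy with 20% had 1989 and 2206.

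Across the 4 mannose groups taken as 1 mean against FAT-MASH, Peg10 rose by 2.02 ± 0.19, the tubulin gene Tubb2a by 1.61 ± 0.16, Mtmr11 by 1.49 ± 0.19, and the division genes Ube2c by 3.16 ± 0.38 and Racgap1 by 2.93 ± 0.39 on the log2 scale. Rgs16 (-2.40 ± 0.33), Car1 (-2.03 ± 0.20), Arl4d (-1.92 ± 0.17), Tsc22d3 (-1.92 ± 0.24), Sult2a8 (-1.73 ± 0.27) and Ip6k2 (-1.45 ± 0.16) were the 6 steepest falls. In FAT-MASH replicates 1, 2 and 3 Tsc22d3 was at 244, 71.9 and 194 CPM. With replicate 2, picked for that, as the only FAT-MASH library, Tsc22d3 was at -0.67, Ip6k2 at -0.72 and Arl4d at -1.05. Khk fell (-0.75 ± 0.13), Mlxipl fell (-0.89 ± 0.15) and Mpi rose (0.56 ± 0.12), and fructose handling genes fell in 8 of 12 cases (10 adjusted over the list alone; camera adjusted p = 1.58e-06; adjusted p = 0.104 with an estimated correlation). In all, 2477 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 993 higher and 1484 lower, against 1406 without FAT-MASH replicate 1 and 1395 without FAT-MASH replicate 2. With 1 library left out, or with voom where named, the call changed for Mpi (lost without FAT-MASH replicate 2, adjusted p 0.056, alternatives 0.000225 to 0.0581).

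The dose was tested as 20% against 5% over both schedules. All 24 cell cycle genes were higher at 20% (median 1.89; 24 adjusted over the list alone), with Hmmr at 3.16 ± 0.35, Ube2c at 3.01 ± 0.27, Cdc20 at 2.98 ± 0.33 and Ckap2 at 2.64 ± 0.33. Inflammatory signalling genes were higher in 11 of 26 cases (13 adjusted over the list alone), such as the chemokine gene Ccl2 (1.81 ± 0.33). Oncofetal genes were higher in 8 of 13 with 0 lower (9 and 1 adjusted over the list alone). Fructose handling genes were lower at 20% in 6 of 12 cases (10 adjusted over the list alone), including Khk (-0.72 ± 0.12), and lipogenic genes in 8 of 23 (10 adjusted over the list alone). Mlxipl (-0.82 ± 0.14) was lower, and Fgf21 (1.38 ± 0.34) and Gdf15 (0.90 ± 0.17) higher. Hamp2 (-2.52 ± 0.34), Acpp (-2.50 ± 0.16), Car1 (-2.28 ± 0.22), Sult2a8 (-2.06 ± 0.28) and Sds (-1.93 ± 0.22) led the falls, while Timp1 (1.03 ± 0.40) and Col1a1 (0.72 ± 0.37) did not pass. The adjusted p of these 5 lists by limma's camera ran from 1.04e-20 to 0.000484, and with an estimated correlation from 0.0822 to 0.323. In all, 3334 genes passed edgeR's test, 1589 higher and 1745 lower. Within each schedule, alternatives added after seeing the data, 87 passed with the prevention groups alone and 3455 with the therapy groups alone. With prevention alone, 19 of 31 named gene values lost their call, among them every gene given here as higher or lower for which it was run except Acpp (-1.27), such as Khk (-0.57), Hmmr (1.58) and Gdf15 (0.22), while Cyp7a1 passed (1.87). With therapy alone 1 lost its call, and Timp1 (2.30) and Col1a1 (1.59) passed. Single libraries, or voom where named, decided the edgeR calls of Timp1 (gained without 20% prevention replicate 1 or 5% therapy replicate 2, adjusted p 0.0138 to 0.0262, alternatives 8.08e-05 to 0.909).

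**Figure D5:**
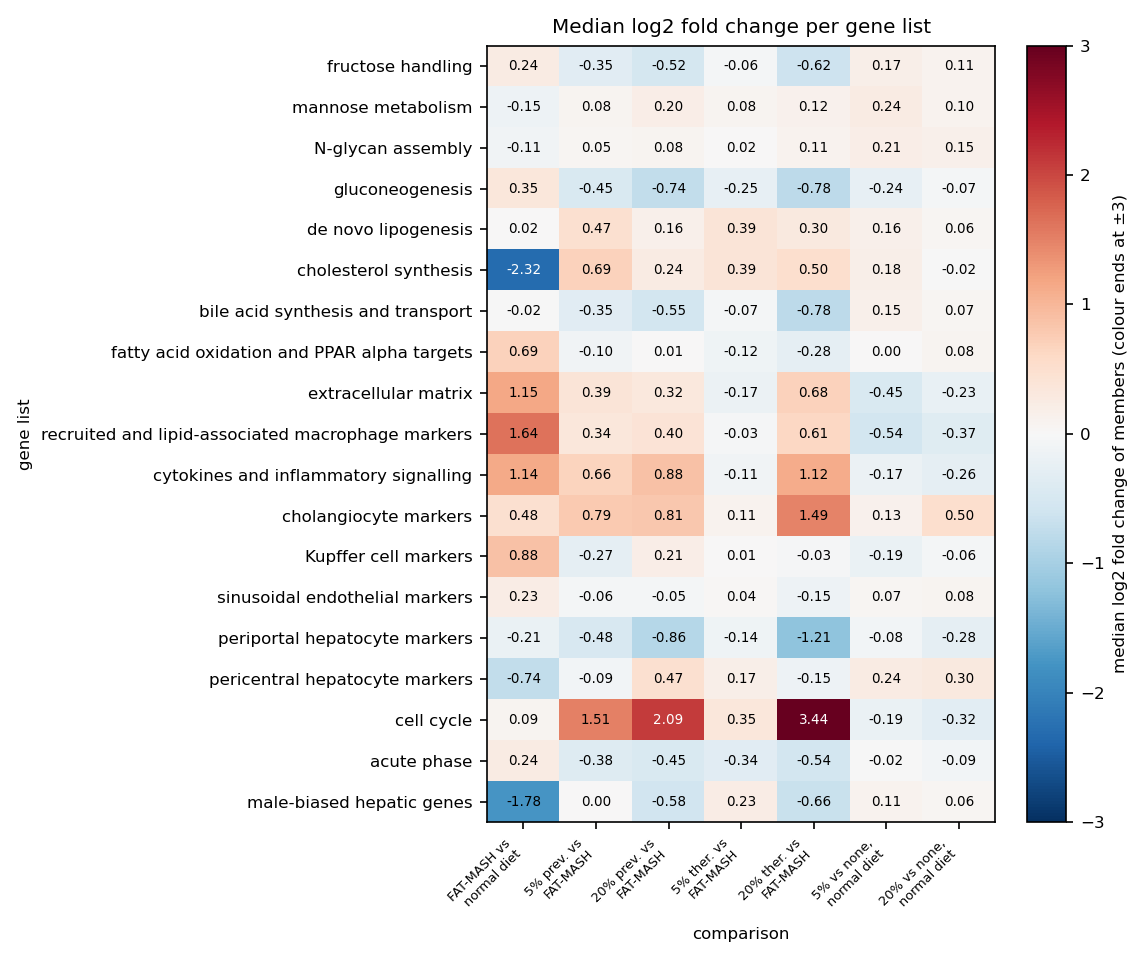
Median log2 fold change of the measured members of 19 gene lists (vertical axis) in 7 comparisons (horizontal axis), printed in each square and shown as colour that ends at 3 in either direction. The cell cycle list ran from -0.32 with 20% mannose on normal diet to 3.44 with 20% therapy on the regimen.

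Prevention against therapy over both doses gave 0 of 19571 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, while 1449 passed at an unadjusted p under 0.05 and DESeq2 called 20. Khk was at -0.23 ± 0.12 and Cyp7a1 at -0.53 ± 0.21. The count was 1 without 20% prevention replicate 1 or 20% therapy replicate 1. Whether the effect of dose differed between the schedules was tested as an interaction, prevention minus therapy, in which 424 genes passed, 228 higher and 196 lower. Cell cycle genes were lower in 18 of 24 cases (24 adjusted over the list alone; median -2.54), so that their step from 5% to 20% was smaller under prevention than under therapy. Bile acid genes were higher in 7 of 21 cases (15 adjusted over the list alone, with 1 lower), among them Slc27a5 (1.20 ± 0.18) and Nr1h4 (0.67 ± 0.14). CAR and PXR targets were higher in 6 of 16 (9 adjusted over the list alone, with 1 lower). Khk did not pass (0.31 ± 0.24, edgeR adjusted p = 0.596). By limma's camera the adjusted p of these 3 lists ran from 7.78e-21 to 5.08e-07, and with an estimated correlation from 0.0792 to 0.146. The count of 424 fell without 5% prevention replicate 1 (72) or 3 (272), 20% prevention replicate 1 (129), 5% therapy replicate 1 (218) or 3 (185), or 20% therapy replicate 1 (119) or 3 (272).

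Each mannose group was also set against normal diet. Extracellular matrix genes were higher than on normal diet in 29 of 34 cases with 5% prevention, 31 with 20% prevention, 13 with 5% therapy and 33 with 20% therapy (29, 32, 25 and 33 adjusted over the list alone). Markers of recruited and lipid-associated macrophages were higher in 16, 16, 10 and 16 of 20 (18, 17, 12 and 17 adjusted over the list alone). Cholesterol synthesis genes were lower in 22, 23, 23 and 23 of 24 (23, 23, 23 and 23 adjusted over the list alone). Timp1 was higher by 4.16 ± 0.71, 3.92 ± 0.71, 2.54 ± 0.72 and 4.84 ± 0.72 in the same order, and Trem2 by 3.48 ± 0.70, 3.27 ± 0.70, 3.05 ± 0.70 and 3.43 ± 0.70; without normal diet replicate 2 Trem2 was at 5.41, 5.20, 5.00 and 5.37. Sprr1a was at least 25.9-fold, 54.4-fold and 282-fold higher with 5% prevention, 20% prevention and 20% therapy, against the floor of 3 counts per library. Hsd3b5 differed from normal diet by -9.15 ± 0.67 with 20% prevention and Susd4 by -5.91 ± 0.44 with 5% therapy. Dbp, an output gene of the clock, was higher by 5.17 ± 0.88 with 5% therapy, at 49.4 ± 26.6 CPM beside 13.5 ± 9.84 in FAT-MASH. Khk differed from normal diet by 0.15 ± 0.17, -0.42 ± 0.17 and -0.34 ± 0.17 with 5% prevention, 20% prevention and 20% therapy, none of which passed. With 5% therapy Khk was higher than on normal diet (0.53 ± 0.17, edgeR adjusted p = 0.046), but did not pass when only these groups were fitted. By edgeR's test 4387, 6511, 2530 and 7057 of 19571 genes differed from normal diet in the 4 groups, against 2687 for FAT-MASH alone. Leaving out 1 library, or voom where named, changed the edgeR calls of Timp1 (lost without normal diet replicate 1, 2 or 3 or 5% therapy replicate 2, adjusted p 0.052 to 0.181, lost with voom, adjusted p 0.266, alternatives 2.11e-08 to 0.266) and Khk (lost without normal diet replicate 1, 2 or 3 or 5% therapy replicate 1 or 3, adjusted p 0.0571 to 0.264, alternatives 0.000447 to 0.264) with 5% therapy, and of Khk (gained without 20% therapy replicate 2, adjusted p 0.0232, alternatives 0.0227 to 0.372) with 20% therapy. The 5% therapy count was 1588 without normal diet replicate 3 and 1415 without 5% therapy replicate 2. All of these list calls passed limma's camera, and with an estimated correlation the adjusted p ran from 0.00486 to 0.0788 for cholesterol synthesis and from 0.172 to 0.466 for the other 2 lists.

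Whether mannose moved genes back toward normal diet was asked over the 2687 genes that differed between FAT-MASH and normal diet. Both comparisons share the FAT-MASH libraries, which alone pulls fold changes apart in sign: in 20 simulated datasets with no mannose effect, 60.8% ± 0.7 (SD) of such genes went the opposite way. Opposite signs were seen in 50.4% of the genes with 5% prevention, 45.1% with 20% prevention, 71.3% with 5% therapy and 45.8% with 20% therapy. Genes past the threshold in both comparisons went the opposite way in 94, 276, 5 and 400 cases and the same way in 57, 375, 1 and 546, against 31.2, 205.3, 0.5 and 290.0 opposite and 29.9, 200, 0.5 and 285.9 same for independent lists. The covariance of the fold changes was -0.127, -0.0918, -0.221 and -0.0686, beside -0.131 simulated for the shared libraries, which leaves 0.004, 0.0392, -0.09 and 0.0624. Without FAT-MASH replicate 1, 2 or 3 the covariances were -0.46, -0.351 and -0.394 for 5% prevention and -0.436, -0.319 and -0.379 for 20% prevention. They were -0.562, -0.455 and -0.475 for 5% therapy and -0.386, -0.28 and -0.342 for 20% therapy, beside -0.293, -0.276 and -0.278 in 10 simulated datasets each, added after seeing the data. What is left was then -0.269 for 5% therapy to -0.004 for 20% therapy, and its sign turned for both 20% groups. The simulated SD was 0.00496 with all libraries and 0.00738 to 0.00968 without 1, so 0.004 and -0.004 have no readable sign. The 3 FAT-MASH libraries cannot be split into 2 parts of at least 2, so part of any excess may come from sharing. Without FAT-MASH replicate 1, 2 and 3 the 5 opposite genes of 5% therapy became 0, 36 and 2. Same-way genes became 20, 20 and 28 for 5% prevention and 354, 351 and 355 for 20% therapy. Without replicate 1 the opposite genes became 31, 171 and 224 for 5% prevention, 20% prevention and 20% therapy. The 94 of 5% prevention became 62 without replicate 3. Same-way genes of 20% prevention became 234 and 224 without replicate 1 and 2.

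On normal diet without the regimen, mannose was tested in the second batch. With 5% mannose, 0 of 18462 genes passed edgeR's test (1039 at an unadjusted p under 0.05, 42 by DESeq2 and 0 by voom). Khk was at 0.38 ± 0.14 and Mpi at 0.38 ± 0.17. With 20% mannose 1 gene rose, the zinc transporter gene Slc39a4 (ENSMUSG00000063354.8, chromosome 15, 76496583 to 76501584), from 47.9 ± 0.158 (n = 2) to 104 ± 11.4 CPM (1.11 ± 0.12). There, Khk was at 0.29 ± 0.13 and Mpi at 0.35 ± 0.16, and 1066 genes passed at an unadjusted p under 0.05, 69 by DESeq2 (26 higher and 43 lower) and 6 by voom (2 and 4). No member of the fructose handling, mannose metabolism or cell cycle lists passed at either dose, and the medians of the cell cycle list were -0.19 and -0.32 (camera adjusted p 0.115 and 0.00806; 0.53 and 0.512 with an estimated correlation). The 5% count was 6 without normal diet replicate 4, 148 without normal diet replicate 5 and 1 without normal-diet 5% mannose replicate 2. The 20% count was 20 and 159 without those normal-diet libraries and 0 without normal-diet 20% mannose replicate 1, 2 or 3. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, single libraries decided the call of Slc39a4 (lost without normal-diet 20% mannose replicate 1, 2 or 3, adjusted p 0.104 to 0.226, alternatives 3e-13 to 0.226), and by limma's camera that of the cell cycle list (lost without normal diet replicate 5, adjusted p 0.0791, alternatives 0.00442 to 0.512).

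Whether mannose acted differently with and without the regimen was tested as an interaction over all 25 libraries with a batch term. Mannose on the regimen was in the first batch only and on normal diet in the second only, so a batch difference stays possible. At 20%, 1211 of 21373 genes passed edgeR's test, 483 higher and 728 lower. The effect on Khk differed by -1.44 ± 0.25 on the log2 scale, lower on the regimen. In all, 4 of 12 fructose handling genes passed, all lower (7 adjusted over the list alone; median -0.59). The others were Slc2a5 (-2.49 ± 0.52), Slc2a9 (-0.67 ± 0.17) and Sord (-0.58 ± 0.15). Cell cycle genes were higher in 14 of 24 cases (18 adjusted over the list alone; median 2.50) and bile acid genes lower in 8 of 21 (11 adjusted over the list alone). At 5%, 112 genes passed, 51 higher and 61 lower; Khk did not (-0.98 ± 0.26), and 0 of 24 cell cycle genes were higher (12 adjusted over the list alone; median 1.62). The adjusted p of these 4 list results by limma's camera ran from 9.9e-10 to 3.14e-06, and with an estimated correlation from 0.0806 to 0.425. Across the genes called at 20% on the regimen, 45.9% had the same sign on normal diet (95% interval 44.1 to 47.7, r = -0.11 across these 2895 genes, which are not independent replicates). The count at 20% was 807 without FAT-MASH replicate 2, 741 without 20% prevention replicate 2 and 545 without normal diet replicate 4. At 5% it ran from 19 without 5% prevention replicate 1 to 333 without normal diet replicate 5. It was 74, 65 and 24 without normal diet replicate 1, 2 and 4, 43, 70 and 45 without FAT-MASH replicate 1, 2 and 3, 66 without 5% prevention replicate 2, and 33 and 51 without normal-diet 5% mannose replicate 1 and 2. With 1 library left out, or with voom where named, the call changed for Khk (gained without normal diet replicate 5, adjusted p 0.0454, alternatives 5.66e-05 to 0.311).

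The enzymes that use mannose itself were tested as a list. Of 15 mannose metabolism genes, 1 was higher and 3 lower on the regimen, 3 and 2 with 20% prevention and 6 and 2 with 20% therapy (1 and 4, 5 and 2, and 7 and 2 adjusted over the list alone). Beside Mpi and Pmm2, Gmds, which starts the route from GDP-mannose to GDP-fucose, rose by 0.99 ± 0.31 and 1.31 ± 0.31. The GDP-fucose transporter gene Slc35c1 rose by 0.46 ± 0.14 and 0.71 ± 0.14. The list passed limma's camera in none of these 3 comparisons (adjusted p 0.0934, 0.402 and 0.24). N-glycan assembly genes, which use mannose to build protein sugars, were higher in 5 of 24 cases with 20% prevention and 8 with 20% therapy, with 1 lower (5, 8 and 1 adjusted over the list alone), such as Rpn1 (0.61 ± 0.12 and 0.76 ± 0.12). The N-glycan list missed the camera threshold with 20% prevention (adjusted p = 0.107) and passed it with 20% therapy (adjusted p = 0.0326, and 0.44 with an estimated correlation). A single library decided the camera call of the N-glycan assembly list (lost without 20% therapy replicate 2, adjusted p 0.129, alternatives 0.0138 to 0.44).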

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

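The tests of hepatocyte share, of mannose without the regimen, of time of day, and with FAT-MASH replicate 2 alone were chosen only after the results were seen.

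Single genes differed between schedules in their response to dose, as the interaction of dose and timing tested it (20% minus 5%, prevention minus therapy; 424 genes in all). The count was 72 and 272 without 5% prevention replicate 1 and 3, 129 without 20% prevention replicate 1, 218 and 185 without 5% therapy replicate 1 and 3, and 119 and 272 without 20% therapy replicate 1 and 3. Higher values were found for Cyp7a1 (2.72 ± 0.42), Acpp (2.46 ± 0.32), Cyp2c54 (2.36 ± 0.44), Etnppl (2.20 ± 0.44), Car1 (2.19 ± 0.43) and S1pr5 (2.18 ± 0.38). Lower values were found for Chrna4 (-3.45 ± 0.87), Tpx2 (-3.32 ± 0.70), Hmmr (-3.16 ± 0.68), Ube2c (-3.08 ± 0.53), Cdc20 (-3.05 ± 0.63), Knstrn (-2.89 ± 0.59) and Gdf15 (-1.37 ± 0.35). Single libraries, or voom where named, decided the edgeR calls of Etnppl (lost without 5% prevention replicate 1 or 20% prevention replicate 1, adjusted p 0.053 to 0.0585, alternatives 2.54e-33 to 0.0585) and Car1 (lost without 5% prevention replicate 1, adjusted p 0.0506, alternatives 6.5e-07 to 0.0506). Chrna4 (lost without 5% prevention replicate 1 or 3, 20% prevention replicate 1, 2 or 3, 5% therapy replicate 1, 2 or 3 or 20% therapy replicate 1 or 3, adjusted p 0.0603 to 0.123, alternatives 1.89e-31 to 0.123) and Tpx2 (lost without 5% prevention replicate 1, 20% prevention replicate 1 or 20% therapy replicate 1, adjusted p 0.0562 to 0.0656, alternatives 1.45e-15 to 0.0656) had calls that changed likewise. Hmmr (lost without 5% prevention replicate 1, 20% prevention replicate 1 or 20% therapy replicate 1, adjusted p 0.0518 to 0.0768, alternatives 5.13e-13 to 0.0768) and Cdc20 (lost without 5% prevention replicate 1 or 20% therapy replicate 1, adjusted p 0.0591 to 0.0636, alternatives 2.34e-24 to 0.0636) had calls that changed likewise. Knstrn (lost without 5% prevention replicate 1 or 20% therapy replicate 1, adjusted p 0.0521 to 0.0572, lost with voom, adjusted p 0.0743, alternatives 2.19e-11 to 0.0743) and Gdf15 (lost without 5% prevention replicate 1 or 2, 20% prevention replicate 1, 2 or 3, 5% therapy replicate 1 or 3 or 20% therapy replicate 1 or 2, adjusted p 0.0501 to 0.146, alternatives 1.01e-09 to 0.146) had calls that changed likewise.

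Between diets, the 20% effect differed in 1211 genes, and in 807 without FAT-MASH replicate 2, 741 without 20% prevention replicate 2 and 545 without normal diet replicate 4. It was higher on the regimen for Ube2c (4.88 ± 0.87), Cyp4a14 (3.58 ± 0.53), Dusp8 (3.55 ± 0.51), Top2a (3.53 ± 0.59), Mybl1 (3.41 ± 0.58) and Nrg1 (3.24 ± 0.68). It was lower for Slc22a7 (-3.98 ± 0.71), Hsd3b5 (-3.63 ± 0.76), Serpina12 (-3.43 ± 0.73), Acpp (-3.09 ± 0.36), Adrb3 (-2.96 ± 0.43), Khk (-1.44 ± 0.25), Mlxipl (-0.98 ± 0.28) and Pklr (-1.29 ± 0.31). Rgs16 had a fitted difference of -10.78, but 0 counts in normal diet replicates 4 and 5, so that value is no measure of size. Ube2c was at 1.75 without normal diet replicate 4, Mybl1 at 1.97 without normal diet replicate 5 and Serpina12 at -5.98 without normal diet replicate 5. Leaving out 1 library, or voom where named, changed the edgeR calls of Ube2c (lost without normal diet replicate 4, adjusted p 0.642, lost with voom, adjusted p 0.395, alternatives 3.55e-18 to 0.642) and Mybl1 (lost without normal diet replicate 5, adjusted p 0.0666, lost with voom, adjusted p 0.123, alternatives 5.05e-14 to 0.123). Nrg1 (lost with voom, adjusted p 0.271, alternatives 1.74e-11 to 0.271) and Rgs16 (lost with voom, adjusted p 0.325, alternatives 2.87e-65 to 0.325) had calls that changed likewise. Mlxipl (lost without FAT-MASH replicate 1 or 2, 20% prevention replicate 2 or 3, normal diet replicate 4 or 5 or normal-diet 20% mannose replicate 1 or 3, adjusted p 0.0509 to 0.167, lost with voom, adjusted p 0.0605, alternatives 5.96e-06 to 0.167) and Pklr (lost without FAT-MASH replicate 2 or normal diet replicate 4, adjusted p 0.0513 to 0.127, alternatives 3.91e-10 to 0.127) had calls that changed likewise.

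The 5% effect differed between diets in 112 genes. Most left-out libraries moved that count by over 1.5 times: 74, 65, 24 and 333 without normal diet replicate 1, 2, 4 and 5, 43, 70 and 45 without FAT-MASH replicate 1, 2 and 3, 19 and 66 without 5% prevention replicate 1 and 2, and 33 and 51 without normal-diet 5% mannose replicate 1 and 2. It was higher on the regimen for Dusp8 (4.11 ± 0.58), Cx3cr1 (3.33 ± 0.77), Id1 (3.29 ± 0.50), Cyp4a14 (2.52 ± 0.57), Btg2 (2.43 ± 0.55) and Slc10a2 (2.40 ± 0.34), and lower for Slc22a7 (-3.21 ± 0.71), Depp1 (-2.62 ± 0.60), Arl4d (-2.54 ± 0.41), Tbx3os1 (-1.96 ± 0.41), Carmil1 (-1.83 ± 0.35) and Cyp2d9 (-1.66 ± 0.35). With 1 library left out, or with voom where named, the edgeR calls changed for Cx3cr1 (lost without normal diet replicate 1, 2 or 4, FAT-MASH replicate 1, 2 or 3, 5% prevention replicate 1, 2 or 3 or normal-diet 5% mannose replicate 1 or 2, adjusted p 0.0517 to 0.17, lost with voom, adjusted p 0.325, alternatives 2.87e-10 to 0.325) and Cyp4a14 (lost without normal diet replicate 2, 4 or 5, FAT-MASH replicate 2 or 3, 5% prevention replicate 1 or 2 or normal-diet 5% mannose replicate 1 or 2, adjusted p 0.0539 to 0.154, alternatives 6.15e-34 to 0.154). Btg2 (lost without normal diet replicate 1, 2 or 4, FAT-MASH replicate 1 or 2, 5% prevention replicate 1 or 3 or normal-diet 5% mannose replicate 1 or 2, adjusted p 0.0518 to 0.204, lost with voom, adjusted p 0.0844, alternatives 5.4e-19 to 0.204) and Slc22a7 (lost without normal diet replicate 1, 2 or 4, FAT-MASH replicate 2 or 3, 5% prevention replicate 1 or 2 or normal-diet 5% mannose replicate 1 or 2, adjusted p 0.0517 to 0.181, alternatives 1.3e-34 to 0.181) had calls that changed likewise. Depp1 (lost without normal diet replicate 1, 4 or 5, FAT-MASH replicate 1, 2 or 3, 5% prevention replicate 1, 2 or 3 or normal-diet 5% mannose replicate 1 or 2, adjusted p 0.0546 to 0.133, lost with voom, adjusted p 0.0614, alternatives 8.37e-36 to 0.133) and Tbx3os1 (lost without FAT-MASH replicate 1 or 2, 5% prevention replicate 1 or 3, normal diet replicate 4 or normal-diet 5% mannose replicate 1 or 2, adjusted p 0.0538 to 0.178, alternatives 0.000245 to 0.178) had calls that changed likewise. Carmil1 (lost without 5% prevention replicate 1, normal diet replicate 4 or normal-diet 5% mannose replicate 1, adjusted p 0.0617 to 0.114, alternatives 5.43e-11 to 0.114) and Cyp2d9 (lost without FAT-MASH replicate 1, 2 or 3, 5% prevention replicate 1, normal diet replicate 4 or normal-diet 5% mannose replicate 1 or 2, adjusted p 0.0546 to 0.155, alternatives 2.15e-14 to 0.155) had calls that changed likewise.

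When the normal-diet libraries were scaled together, Gpnmb stood at 40.8 CPM in normal diet replicate 2, and the next of the 5 normal-diet libraries was at 0.979 CPM. That gap was 0.976 of the range of the 5 libraries. It was sought in the 19 key genes, and chance puts about 1 in 20 groups past the threshold used.

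Cell cycle genes rose with 20% mannose on the regimen (medians 2.09 in prevention and 3.44 in therapy, camera adjusted p = 0.266 and 0.0960 with an estimated correlation). A lower share of hepatocyte RNA alone would raise markers of all other cell types alike, which was not seen. Joined to other changes in those cells it stays open, as the 100 most abundant genes fell. In 20% therapy the median of sinusoidal endothelial markers was -0.15 (upper quartile 0.07, and 0.03 in prevention). That of cholangiocyte markers was 1.49 (lower quartile 0.88, and 0.52 in prevention). Kupffer markers were at -0.03 (upper quartile 0.86, and 0.88 in prevention), or -0.10 with the endothelial ones. Medians of stellate, recruited macrophage, neutrophil, T and NK, and B and plasma cell markers were 0.55, 0.61, 1.03, 0.22 and 0.06 in therapy. All lay under the cell cycle lower quartile of 2.10 (0.99 in prevention). The upper quartile passed it for cholangiocyte (2.67, 2.01 in prevention) and, in prevention, neutrophil markers (1.31). Scaling is argued against by a median of 3.76 in therapy with library totals alone, where 24 members passed, and mannose acting without the regimen by the median of -0.32 with 20% on normal diet. An increase of cholangiocytes or of dividing cells of another type, as a hypothesis, and differences in cage, day or time of collection stay open.

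The 6 largest falls in the mean of the mannose groups (Rgs16, Car1, Arl4d, Tsc22d3, Sult2a8 and Ip6k2) had a median of -1.92. Per1, a clock and glucocorticoid-responsive gene, was at 34.2, 3.93 and 38.6 CPM and Tsc22d3 at 244, 71.9 and 194 CPM in FAT-MASH replicates 1, 2 and 3. With replicate 2 as the only FAT-MASH library Tsc22d3 was at -0.67, Ip6k2 at -0.72, Arl4d at -1.05, Rgs16 at -1.69, Car1 at -1.78 and Sult2a8 at -1.81, but it was picked for its low Per1 and Tsc22d3, so these values decide nothing. Time of day cannot be told apart from an effect of mannose: the median of clock genes that run against Dbp minus that of genes in step with it was 0.53, 0.45, -0.67 and 0.86 in 5% prevention, 20% prevention, 5% therapy and 20% therapy against FAT-MASH (spread 0.19 to 0.22), which cancels to 0.11 in their mean. Acute stress or handling of the FAT-MASH mice and mannose itself stay open too.

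Fructose handling genes fell with 20% mannose on the regimen (medians -0.52 and -0.62, camera adjusted p = 0.118 and 0.0821 with an estimated correlation). The 100 genes with the highest mean CPM had medians of -0.40 in 20% prevention and -0.61 in 20% therapy. A general fall of abundant hepatocyte transcripts would thus fit the list. Whether Khk (-1.15 and -1.07) fell beyond those 100 genes was not tested. Scaling stays undecided, with a median of -0.33 for 20% prevention under library totals alone. Mannose acting without the regimen is argued against by the median of 0.11 with 20% on normal diet, in another batch. A lower need for these enzymes on mannose is a hypothesis that was not tested.

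Other splits of the same libraries were refitted for each count. With 3 against 3 there are 10 splits, too few for a share under 0.05, and the real and highest other counts were 2819 and 0 for FAT-MASH against normal diet. Against FAT-MASH they were 386 and 0 for 5% prevention, 2859 and 0 for 20% prevention, 1 and 7 for 5% therapy, and 3989 and 0 for 20% therapy, and against normal diet 4196, 6342, 2025 and 6790 in that order, with 0 the highest other each time. For 5% therapy, 4 of the 10 splits called as many genes. Of 60 splits in a model of 2 groups, only the real one called as many genes for the mean of the mannose groups and dose. It called 49 (highest other 12) and 2439 (346), which argues against chance in this model alone. For timing, and for dose by timing in the same simple model, the splits say nothing of chance: the real split called 0, so that all 60 had to call as many. The highest other, 2439, is the split by dose, which points to a structure of the samples and says nothing of the 424 genes.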

How the results depend on the processing

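The settings with FAT-MASH replicate 2 alone, or within 1 dose or schedule, were chosen after seeing the data. The 246 named gene values past the threshold kept direction in all settings run for them. Of all named gene values, past the threshold or not, RLE size factors left 477 on the same side and moved 1 below and 1 above it, DESeq2 left 466 and moved 10 above, voom left 438 and moved 25 below and 16 above, and leaving out 1 library left 3774, moved 228 below and 41 above. With 31298299 to 56010646 counts per library, changes of 1.5-fold were mostly missed in simulated data, so genes that did not pass are not shown to be unchanged. Except where stated, the cause was not tested.

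DESeq2 called 943 genes for 5% prevention, 85 for 5% therapy, 20 for timing, 1036 for dose by timing, 42 and 69 for 5% and 20% on normal diet, and 495 for the difference between diets at 5%. Without a filter on low counts the same comparisons gave 1254, 339, 228, 1364, 222, 254 and 897. Voom gave 676 for 5% prevention, 4 for 5% therapy, 1043 for dose by timing and 6 for 20% on normal diet. Fitting only the groups compared gave 1 for 5% therapy, 280 for dose by timing, 0 for 20% on normal diet and 43 for the difference at 5%. All 25 libraries together gave 7 and 32 for 5% and 20% on normal diet, 10 for 5% therapy (3 higher and 7 lower), and 8 genes called with opposite signs for the regimen and 5% therapy. With FAT-MASH replicate 2 as the only FAT-MASH library, picked for its low Per1 and Tsc22d3 and assumed to vary like the others, counts were 711 against normal diet, 2, 970, 0 and 1889 for 5% prevention, 20% prevention, 5% therapy and 20% therapy, and 342 for their mean. The dose within prevention gave 87, and the timing within 5% and 20% gave 38 and 16. Whether more genes were called higher or lower turned in some settings for the regimen, all 4 mannose groups against FAT-MASH, dose, dose by timing, both 5% groups against normal diet, 20% on normal diet and the difference between diets at 5%. Of 612 list tests 304 passed by camera, 177 by fry and 8 with an estimated correlation.

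Leaving out each library in turn gave 127 to 344 genes for 5% prevention, 1938 to 2476 for 20% prevention, 0 to 43 for 5% therapy, 1395 to 2542 for the mean, 0 to 1 for timing, 72 to 583 for dose by timing, and 1415 to 2509 for 5% therapy against normal diet. On normal diet it gave 0 to 148 and 0 to 159 for 5% and 20%, and for the difference between diets 19 to 333 and 545 to 1253. Genes called with opposite signs for the regimen and for mannose numbered 31 to 88, 171 to 207, 0 to 36 and 224 to 291 for 5% prevention, 20% prevention, 5% therapy and 20% therapy. The direction by camera turned for 3 lists, whose medians were: extracellular matrix in 20% prevention -0.08 without its replicate 3 (-0.08 to 0.54), lipid-associated macrophage markers for timing 0.00 without 5% therapy replicate 3 (-0.07 to 0.39), and the unfolded protein list -0.01 without normal-diet 5% mannose replicate 2 (-0.01 to 0.35).

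Same-numbered replicates of different groups share only a number: the 45 such pairs had correlations of -0.16 to 0.18 (mean -0.011) and 1 of 18 libraries correlated best with its own number. With the replicate block, counts stayed within 1.5 times (for example 376 for 5% prevention and 2801 for 20% prevention), and 8 named gene values moved below the threshold and 1 above.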

Other observations

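The gene lists here were fixed beforehand, while the genes followed across groups and the gene without a symbol were picked after their values were seen, and no test was chosen for them.

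The imprinted gene Peg10 went from 2.98 ± 0.47 CPM in FAT-MASH to 11.1 ± 0.351, 15 ± 2.21, 8.08 ± 2.9 and 16 ± 1.83 CPM with 5% prevention, 20% prevention, 5% therapy and 20% therapy. In that order the imprinted RNA H19 went from 24.2 ± 18.2 CPM to 1.26 ± 0.584, 1.04 ± 1.14, 4.4 ± 3.59 and 0.846 ± 0.847 CPM. The zinc transporter gene Slc39a4 stood at 60.2 ± 13.9 CPM in first-batch normal diet and 85.7 ± 5.49 CPM in FAT-MASH, and at 121 ± 20.2 and 127 ± 10.4 CPM with 20% prevention and therapy. Cyp2e1, the cytochrome that activates carbon tetrachloride, was at 4670 ± 443 CPM in FAT-MASH, 2520 ± 422 with 20% prevention and 1420 ± 265 with 20% therapy.

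On the regimen alone, interferon response genes rose in 11 of 22 cases and fell in 1 (11 and 1 adjusted over the list alone), with Oas1a at 1.84 ± 0.29. Xenobiotic targets of CAR and PXR fell in 7 of 16 (7 adjusted over the list alone), with Cyp2c29 at -2.28 ± 0.23 and Cyp2b10 at -3.10 ± 0.61. Genes of the unfolded protein and integrated stress response rose in 5 of 22 and fell in 10 (6 and 12 adjusted over the list alone), with the chaperone partner Sdf2l1 at -1.61 ± 0.17 and Sesn2 at 1.07 ± 0.18. The adjusted p by limma's camera was 0.000351, 9.4e-05 and 0.000474, and from 0.30 to 0.351 with an estimated correlation. With 20% prevention, targets of the oxidative stress factor NRF2 rose in 8 of 19 cases and fell in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.00367; 0.562 with an estimated correlation). Single libraries, or voom where named, decided the camera call of the oxidative stress response (NRF2) list (lost without 20% prevention replicate 2, adjusted p 0.063, alternatives 6.13e-08 to 0.562).

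The gene without a symbol ENSMUSG00000119584 held 0.269% to 0.604% of counts in the first batch and 4.03% to 8.52% in the second, and 2.21% of all counts.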
